A study of Homo sapiens with 40 samples.

How the data were processed

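Read counts per gene were taken from 4 deposited tables, in the unit counts as the authors gave them, for cytoplasmic and polysomal RNA of the small cell lung cancer lines H69, H196 and H69M. Per the labels, cells grew in RPMI medium with serum. Also per the labels, cytoplasmic RNA came from a hypotonic lysate, polysome-bound RNA came from sucrose fractions after polysome profiling, and libraries were made with a NEBNext Ultra kit. Per the labels the authors mapped reads to GRCh38 (hg38) with STAR and counted them with HTSeq, with no versions, annotation release or strand setting stated. Each table holds 3 H69 libraries and 3 libraries of the other line, so that H196 and H69M each have their own H69 control (the H196 set and the H69M set; H69 replicates 4, 5 and 6 belong to the H69M set). The labels list 40 samples, of which 24 were analysed; the 16 samples of H82, H82R, H209 and H209A were not analysed here. The tables have 56832 genes each, 56815 of them shared by all, since 17 names per table were changed to dates. Genes keep the names of the tables, and members of lists were matched by current or older symbol.

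Comparisons were made with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, a quasi-likelihood F test and Benjamini-Hochberg adjustment, with a call at adjusted p under 0.05. They were H196 against H69 and H69M against H69 in each fraction, the interaction of line and fraction (polysome association), and the H69M effect minus the H196 effect in each fraction. Log2 changes carry ± standard errors (the absolute log2 change divided by the root of F), and CPM values carry ± standard deviations, with n = 3 libraries per group. A fold against a group at 0 reads was taken against a floor of 3 counts over the group and is given as at least that fold; with 1 to 3 reads the ratio has a 95% counting interval. List medians and differences of effects use the same floor. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and adjusted over the lists of a comparison. List calls made with all libraries, and for which no second value is given, also held with an estimated correlation.

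The comparisons, the 26 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The identity lists were neuroendocrine, non-neuroendocrine, lineage regulators, Notch, mesenchymal, epithelial, YAP/TAZ targets and focal adhesion. The signalling and defence lists were receptor tyrosine kinase and ERK, drug transport and detoxification, antigen presentation and interferon, and proliferation. The translation lists were cytosolic ribosomal proteins, other 5 prime TOP mRNAs, translation initiation factors and 60S assembly. The stress and metabolism lists were ATF4 targets, endoplasmic reticulum chaperones, oxidative phosphorylation, glycolysis and lipid synthesis. The remaining lists were mitochondrially encoded mRNAs, nuclear long noncoding RNAs, snoRNA host noncoding RNAs, blood cell markers and endothelial markers. Named genes were EIF6 and up to 2 called members each way per list, by absolute log2 change among those with a mean of at least 1 log2 CPM, with a fixed set of central genes whatever their result. Further named genes were the 5 largest called changes each way with a mean of at least 3 log2 CPM and groups that did not overlap. For polysome association that mean had to hold in both fractions, and for differences between effects the 5 were taken among called genes with effects of opposite sign. XIST, Y-linked genes and features without a symbol were passed over.

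Depth ran from 12125069 to 18123696 counted reads per library in the H196 set and from 28631033 to 43642668 in the H69M set. Each test was tested on simulated counts at the measured spread, with changes of 2-, 4- and 16-fold added to 67, 67 and 66 genes. For 4-fold changes it recovered 1.49% in H196 cytoplasmic RNA, 91.0% in H196 polysomal RNA, 1.49% for H196 association, 95.5% in H69M cytoplasmic RNA, 89.6% in H69M polysomal RNA and 88.1% for H69M association. For the differences between effects it recovered 2.99% (cytoplasmic) and 64.2% (polysomal) at 4-fold, and 57.6% or more at 16-fold in every comparison. False calls numbered 0 to 10 per comparison.

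Libraries of like number were checked as pairs by correlating, across genes, their deviations from the group means. Cytoplasmic and polysomal libraries of like number gave r = 0.36, 0.32 and 0.36 for H69 and 0.47, 0.67 and 0.12 for H196 in the H196 set, 0.58, 0.25 and 0.44 for H69 and -0.12, 0.24 and -0.16 for H69M in the other set. Between lines, polysomal H69M and H69 libraries of like number gave 0.20, 0.28 and 0.13. The H69M fractions did not pair as a whole, since the unlike numbers 2 and 4 gave 0.24 and 0.20. The other pairs of groups did not pair either (H196 and H69: 0.39, -0.33 and -0.36 cytoplasmic, 0.23, -0.33 and 0.29 polysomal; H69M and H69 cytoplasmic: -0.01, 0.26 and -0.18). A block for library number was an alternative, given beside a result where it changes it.

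Alternatives were the DESeq2 1.42.0 Wald test, DESeq2 size factors, library totals, no low-count filter, a filter at 50 reads on average, a call only at an absolute log2 change of at least 1, limma-voom. Further ones were each library left out in turn, the block, a dispersion shared with the other fraction, the H69 libraries of the other set, and for association a log2 ratio per library pair. Robust quasi-likelihood, voom with quality weights, removal of the GC trend of each library, list tests limited to members with more than 3 reads, and the omission of H69 cytoplasmic replicate 3 of the H196 set as a whole comparison were added after seeing the data. The limit to more than 3 reads held for every group in polysome association and for H69 of both sets in the differences between effects. The H69M effect minus the H196 effect used genes present in both sets of tables. No batch, date or run is given in the labels, so set and line cannot be told apart from any batch except by the separate H69 libraries.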

Results

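Cytoplasmic and polysomal RNA from the small cell lung cancer lines H196 and H69M was compared with RNA from H69, with 3 libraries per group and separate H69 libraries for each comparison. EIF6 encodes eIF6, a factor that binds the large ribosomal subunit and keeps it from joining the small one. In cytoplasmic RNA EIF6 rose 1.37-fold in H69M (log2 0.46 ± 0.14, adjusted p = 0.0293), from 120 ± 17.2 to 165 ± 8.49 CPM, with all 3 H69M libraries above all 3 H69 libraries. In polysomal RNA of the same lines EIF6 stood at 510 ± 107 CPM in H69M and 447 ± 109 CPM in H69 (log2 0.19 ± 0.26, adjusted p = 0.788). In H196 the EIF6 log2 change was 1.00 ± 0.67 in cytoplasmic RNA (adjusted p = 0.287) and -0.38 ± 0.30 in polysomal RNA (adjusted p = 0.279). The cytoplasmic H69 group included replicate 3 at 8.96 CPM of library totals, against 59.3 and 55.2 CPM in replicates 1 and 2. With the H69 libraries of the other set the H196 cytoplasmic change was -0.52 (adjusted p = 0.183). Polysome association of EIF6, the change of its polysomal over its cytoplasmic level, had a log2 change of -1.40 ± 0.77 in H196 (adjusted p = 0.648) and -0.17 ± 0.30 in H69M. The H69M effect on EIF6 minus the H196 effect was -0.58 ± 0.70 in cytoplasmic RNA (adjusted p = 0.624) and 0.75 ± 0.42 in polysomal RNA (adjusted p = 0.155). The H69M cytoplasmic call for EIF6 ended without H69 replicate 4 (log2 0.37) or 5 (0.50), without H69M replicate 2 (0.44) or 3 (0.46), with library totals (0.32) and with a shared dispersion (0.39). That call also ended with the other H69 libraries (log2 2.05, adjusted p = 0.0759). Its adjusted p stayed under 0.05 in 12 of 19 alternatives and ran from 0.00432 to 0.244, and the H196 polysomal change was called with library totals (log2 -1.04) and with the other H69 libraries (-2.99). The H69M polysomal change was called with the other H69 libraries (log2 2.65, adjusted p = 1.15e-05) and the polysomal difference of effects with library totals (1.22, adjusted p = 0.0146). Polysomal EIF6 differed within H69, at 105, 121 and 70.3 CPM of library totals in the H196 set and 381, 504 and 446 in the H69M set. Both polysomal calls with the other H69 libraries thus cannot be told apart from this gap between the sets.

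**Figure D1:**
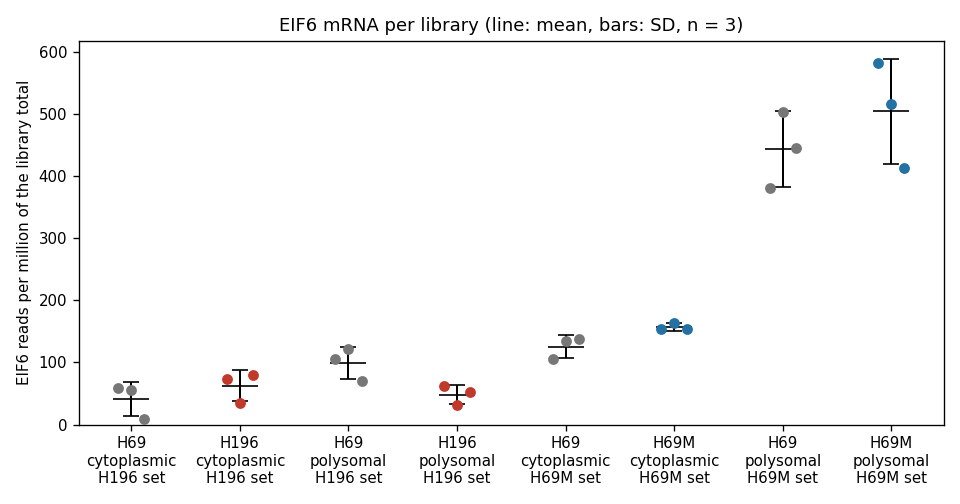
EIF6 level in CPM of library totals for each library of both sets and both fractions. Points show libraries, horizontal lines group means and vertical bars standard deviations. H69 cytoplasmic replicate 3 of the H196 set lay at 8.96 CPM, against 59.3 and 55.2 CPM in the other libraries of its group. Polysomal H69 libraries lay at 70.3 to 121 CPM in the H196 set and at 381 to 504 CPM in the H69M set.

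In H196 cytoplasmic RNA the granule protein gene CHGA fell at least 467-fold, the vesicle gene SYT4 at least 3819-fold, and the synaptophysin gene SYP fell 44.5-fold (log2 -5.48 ± 1.13). Of 25 neuroendocrine genes tested 21 fell, 0 rose and 4 were not called (23 fell when adjusted over the list alone; median log2 -7.68, camera adjusted p = 5.74e-12). The intermediate filament gene VIM rose at least 67532-fold and the collagen gene COL3A1 at least 24149-fold. Of 39 mesenchymal genes 35 rose and 4 were not called (36 adjusted over the list alone; median log2 8.34, camera adjusted p = 7.84e-18). Among 24 non-neuroendocrine genes 21 rose and 3 were not called (22 adjusted over the list alone; camera adjusted p = 5.28e-12). IFITM3, an antiviral membrane protein gene, rose at least 31384-fold and CAV1, which builds caveolae, at least 8230.3-fold. Without H69 replicate 3, which stands apart from its group, these lists were not called with an estimated correlation (neuroendocrine adjusted p = 0.166, mesenchymal and non-neuroendocrine adjusted p = 0.124), nor was any other list of this comparison.

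Lineage regulators moved both ways in H196 cytoplasmic RNA: 4 of 16 rose, 9 fell and 3 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.137). YAP1, a coactivator of the Hippo pathway, rose at least 1238-fold and its paralog WWTR1 3516-fold (counting interval 973 to 29042). MYCN fell at least 13668-fold and MYC rose 8.73-fold (log2 3.13 ± 0.50). REST, the repressor of neuronal genes, had 2 reads over the H69 libraries and a ratio of 812 (counting interval 224 to 6715). HES1, a Notch target, rose 7.42-fold (log2 2.89 ± 0.60). The receptor gene NOTCH3 rose with a ratio of 15403 (4264 to 127198) and the inhibitory ligand gene DLL3 fell 304-fold (log2 -8.25 ± 1.58). Of 17 Notch genes 7 rose, 5 fell and 5 were not called (7 and 6 adjusted over the list alone), with a median log2 of -0.04, a mean of 0.46 and camera adjusted p = 0.558 upward. EPCAM, an epithelial adhesion gene, fell 2125-fold (log2 -11.05 ± 1.13), CDH1 fell 4.99-fold (log2 -2.32 ± 0.56), ST14 fell at least 3539-fold and KRT19 at least 1609-fold. CDH3 (log2 4.43 ± 0.97) and KRT18 (1.63 ± 0.50) rose. In total 14 of 19 epithelial genes fell, 2 rose and 3 were not called, also when adjusted over the list alone (camera adjusted p = 0.000183; adjusted p = 0.365 with an estimated correlation).

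In the same RNA YAP/TAZ targets rose in 15 of 21 cases with 6 not called (15 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.4e-08). The Hippo kinase gene LATS2 rose at least 1239-fold and ANKRD1 at least 1198-fold. Focal adhesion genes rose in 25 of 34 cases, 1 (ITGA6, log2 -2.57 ± 0.70) fell and 8 were not called (27 and 1 adjusted over the list alone; camera adjusted p = 1.9e-09; adjusted p = 0.0797 with an estimated correlation). Receptor tyrosine kinase and ERK genes rose in 16 of 26 cases and fell in 2, with 8 not called, also adjusted over the list alone (camera adjusted p = 0.000118; adjusted p = 0.0797 with an estimated correlation). The receptor gene AXL had a ratio of 7129.5 (counting interval 2439 to 34575), PDGFRB one of 6997 (1255 to 276395). CD44 rose 7.33-fold (log2 2.87 ± 0.48) and the ERK phosphatase gene DUSP4 fell 18.5-fold. Antigen presentation and interferon genes rose in 23 of 26 cases with 3 not called, also adjusted over the list alone, IFI44 at least 2329-fold (camera adjusted p = 1.27e-10; adjusted p = 0.0841 with an estimated correlation). Drug transport and detoxification genes rose in 12 of 20 cases and fell in 2, with 6 not called (13 and 2 adjusted over the list alone; camera adjusted p = 0.00112; adjusted p = 0.0895 with an estimated correlation). The DNA repair gene MGMT rose at least 591-fold and GSTM1 at least 214-fold, while ALDH1A1 fell 745-fold (log2 -9.54 ± 0.66) and AKR1C2 fell 42.8-fold.

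In H196 cytoplasmic RNA proliferation genes rose in 4 of 33 cases and fell in 3, with 26 not called (4 and 1 adjusted over the list alone; camera adjusted p = 0.768). TK1 changed by log2 3.51 ± 0.95 and EZH2 by -2.24 ± 0.39. Endoplasmic reticulum chaperones rose in 6 of 21 cases, 1 fell and 14 were not called, also adjusted over the list alone (camera adjusted p = 0.15). PDIA4 rose 4.48-fold, HSP90B1 rose 4.13-fold and ERO1B fell 322-fold. The remaining translation and metabolism lists had camera adjusted p from 0.401 to 0.98, oxidative phosphorylation with a median of 0.13, a mean of -0.16 and a downward test. Cytosolic ribosomal protein mRNAs fell in 2 of 77 cases (0 adjusted over the list alone; median log2 0.01, camera adjusted p = 0.98). ATF4, the integrated stress response factor, had log2 -0.15 ± 0.79. Across all 15796 genes tested 2679 rose and 2975 fell. The contractile genes CNN1 (at least 14224-fold) and CALD1 (at least 12051-fold) were among the top rises. The neuropeptide gene GRP fell at least 5404-fold, NELL1 at least 4640.4-fold and HEPACAM2 at least 4083-fold. H69 cytoplasmic replicate 3 had 17108 genes detected, against 24161 and 24427 in replicates 1 and 2, and 15.4% mitochondrial reads against 7.29% and 7.25%. Without it 4459 genes rose and 5027 fell, of which 2678 and 2967 were called with it too. In that case chaperones rose as a list (12 rose, 1 fell, camera adjusted p = 0.0397; adjusted p = 0.309 with an estimated correlation). Calls ended without single libraries (H69 replicate 1 or 2, or H196 replicate 1, 2 or 3) for CDH1 (log2 -2.35 to -1.81, not H69 replicate 2), KRT18 (1.19 to 1.90, not H196 replicate 2), ITGA6 (-2.82 to -2.23, H196 libraries), HSP90B1 (1.74 to 1.96, H69 libraries and H196 replicate 1) and TK1 (3.30 to 3.67, H69 replicate 2, H196 replicates 1 and 3). KRT18 was also not called with library totals (1.26) or with the GC trend removed (0.55), and a block for library number ended the calls of KRT18 (1.56) and CDH1 (-2.21).

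**Figure D2:**
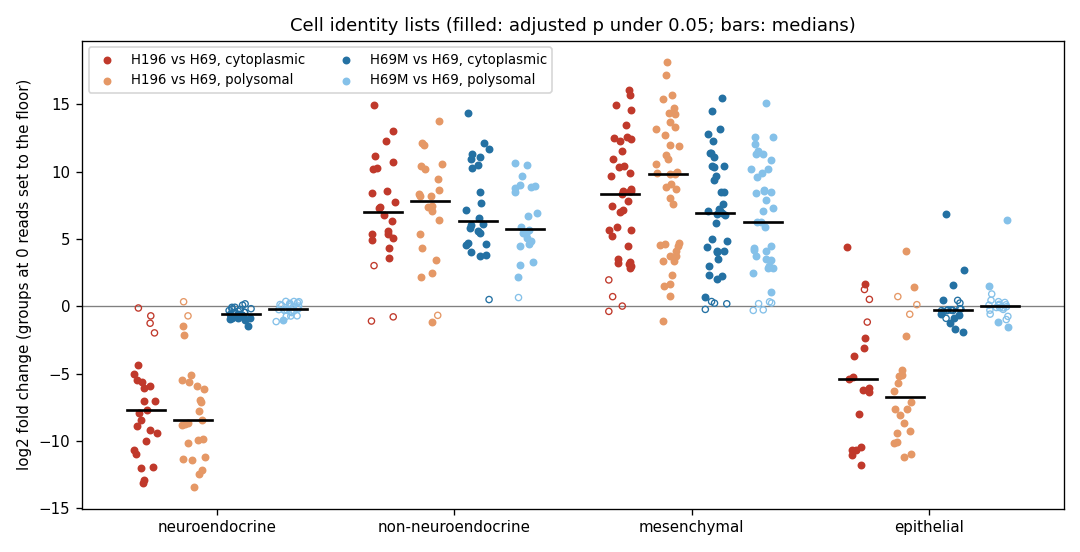
Log2 changes of the members of lists of cell identity genes against H69 in cytoplasmic and polysomal RNA of H196 and H69M, points for genes (groups at 0 reads set to the floor), bars for medians. The cytoplasmic neuroendocrine median lay at -7.68 in H196 and -0.56 in H69M, the mesenchymal median at 8.34 and 6.95.

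In H196 polysomal RNA EPCAM fell by 10.96 ± 0.51 on the log2 scale and INSM1, a zinc finger factor of neuroendocrine cells, fell by 13.43 ± 0.50. Neuroendocrine genes fell in 23 of 25 cases with 2 not called, also adjusted over the list alone (median log2 -8.41, camera adjusted p = 1.81e-09), SYT4 at least 2642-fold. VIM rose with a ratio of 425201 to its single H69 read (counting interval 76315 to 16794600), COL3A1 likewise with 219289. Of 39 mesenchymal genes 38 rose and 1 fell, also adjusted over the list alone (median log2 9.81, camera adjusted p = 2.66e-17). YAP1 rose at least 1353-fold, REST at least 651-fold, AXL at least 10286-fold, the membrane repair gene MYOF with a ratio of 17419 (4821 to 143840) and CAV1 with 5496 (1521 to 45389). Among 16 lineage regulators 4 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.118). Epithelial genes fell in 17 of 22 cases and rose in 2, with 3 not called (17 and 3 adjusted over the list alone), ST14 by log2 -11.15 ± 0.49 (camera adjusted p = 7.59e-05; adjusted p = 0.128 with an estimated correlation). Focal adhesion genes rose in 31 of 34 cases and 1 fell (32 and 1 adjusted over the list alone), the integrin gene ITGA1 by log2 10.88 ± 0.41 (camera adjusted p = 1.95e-11). Non-neuroendocrine genes rose in 20 of 22 cases and 1 fell (camera adjusted p = 1.81e-09), and YAP/TAZ targets in 18 and 1 of 21 (1.55e-08). Antigen presentation and interferon genes rose in 23 of 26 cases (camera adjusted p = 1.97e-10), and all 3 counts were the same adjusted over the list alone. Receptor tyrosine kinase and ERK genes rose in 17 of 26 cases and fell in 3 (18 and 3 adjusted over the list alone; camera adjusted p = 7.59e-05; adjusted p = 0.0837 with an estimated correlation). Drug transport genes rose in 14 and fell in 4 of 20 cases, also adjusted over the list alone (camera adjusted p = 0.00124; adjusted p = 0.323 with an estimated correlation). Notch genes rose in 8 of 17 cases and fell in 8, also adjusted over the list alone (camera adjusted p = 0.688).

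Ribosomal protein mRNAs were lower in H196 polysomal RNA: of 74 cytosolic ribosomal protein genes 49 fell, 1 (RPL5, log2 0.84 ± 0.22) rose and 24 were not called, also adjusted over the list alone (median log2 -1.10). Camera gave adjusted p = 4.82e-05 downward for this list, and adjusted p = 0.542 with an estimated correlation. RPS25 fell 7.17-fold (log2 -2.84 ± 0.35) and RPS26 5.75-fold (log2 -2.52 ± 0.31), both small subunit genes. Oxidative phosphorylation genes fell in 24 of 40 cases and rose in 4, with 12 not called, also adjusted over the list alone (camera adjusted p = 0.0373; adjusted p = 0.526 with an estimated correlation). ATP5D changed by log2 -2.48 ± 0.30 and SDHA by 1.48 ± 0.28. Mitochondrially encoded mRNAs rose in 10 of 12 cases with 2 not called, also adjusted over the list alone (camera adjusted p = 0.00726; adjusted p = 0.409 with an estimated correlation). MT-ND6 rose by log2 1.93 ± 0.39 and MT-CO2 by 1.85 ± 0.28. MT-CO2 and MT-ND6 were not called with the other H69 libraries (log2 0.41 and 0.29). Other 5 prime TOP mRNAs, which share the growth-regulated start of ribosomal protein mRNAs, rose in 5 of 22 cases and fell in 7, also adjusted over the list alone (camera adjusted p = 0.829). NAP1L1 changed by log2 1.59 ± 0.26 and BTF3 by -1.65 ± 0.23. Translation initiation factors rose in 11 of 35 cases and fell in 6 (8 and 5 adjusted over the list alone; camera adjusted p = 0.379). Called factors were EIF5A2 (log2 3.94 ± 0.38), the scaffold gene EIF3A (1.72 ± 0.24) and EIF1 (-1.25 ± 0.30). The 60S assembly list rose in 9 of 37 cases and fell in 9, also adjusted over the list alone, NOC2L by log2 1.93 ± 0.26 and the rRNA methyltransferase gene FBL by -2.17 ± 0.23. Its median was 0.08, its mean -0.14 and camera adjusted p = 0.875 upward.

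Endoplasmic reticulum chaperones rose in 13 of 21 cases in H196 polysomal RNA and fell in 2 (13 and 3 adjusted over the list alone), HSP90B1 6.94-fold and PDIA6 6.00-fold (camera adjusted p = 0.0154; adjusted p = 0.128 with an estimated correlation). Lipid synthesis genes rose in 10 of 22 cases and fell in 2 (8 and 2 adjusted over the list alone), IDI1 4.15-fold (camera adjusted p = 0.0373; adjusted p = 0.526 with an estimated correlation). ATF4 fell by 1.13 ± 0.41 on the log2 scale (adjusted p = 0.0295). Of 25 ATF4 targets 15 fell and 6 rose, also adjusted over the list alone, DDIT4 31.3-fold lower and VLDLR 5.77-fold higher (camera adjusted p = 0.688). Glycolysis genes rose in 9 of 23 cases and fell in 9, also adjusted over the list alone, the phosphofructokinase gene PFKP by log2 2.81 ± 0.28 and the neuronal enolase gene ENO2 by -2.72 ± 0.25. For this list the median was -0.33, the mean 0.13 and camera adjusted p = 0.86 upward. Proliferation genes rose in 14 of 33 cases and fell in 7, also adjusted over the list alone, MCM2 4.92-fold higher and E2F2 6.61-fold lower (camera adjusted p = 0.231). Across 14779 genes 4562 rose and 5283 fell (46.3% of the calls higher). MSN (at least 42666-fold), COL12A1 (at least 34382-fold) and COL5A3 (at least 22615-fold) were among the top rises. HEPACAM2 (at least 2388-fold), DCX (at least 1918-fold), KCNA1 and XKR7 (each at least 1389-fold) were among the top falls. With library totals in place of TMM 3067 rose and 7314 fell (29.5% higher). The median of all genes shifted by -0.64, past the median of the lipid list (0.59), and the calls of that list (camera adjusted p = 0.212) and of RPL5 (log2 0.20) were lost. RPL5 was not called without H69 replicate 2 (0.76), nor ATF4 without H69 replicate 1 (-0.59) or H196 replicate 2 (-0.89) or 3 (-0.99). With a dispersion shared with the cytoplasmic libraries neither RPL5 (log2 0.85, adjusted p = 0.0817) nor ATF4 (-1.12, adjusted p = 0.196) was called.

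**Figure D3:**
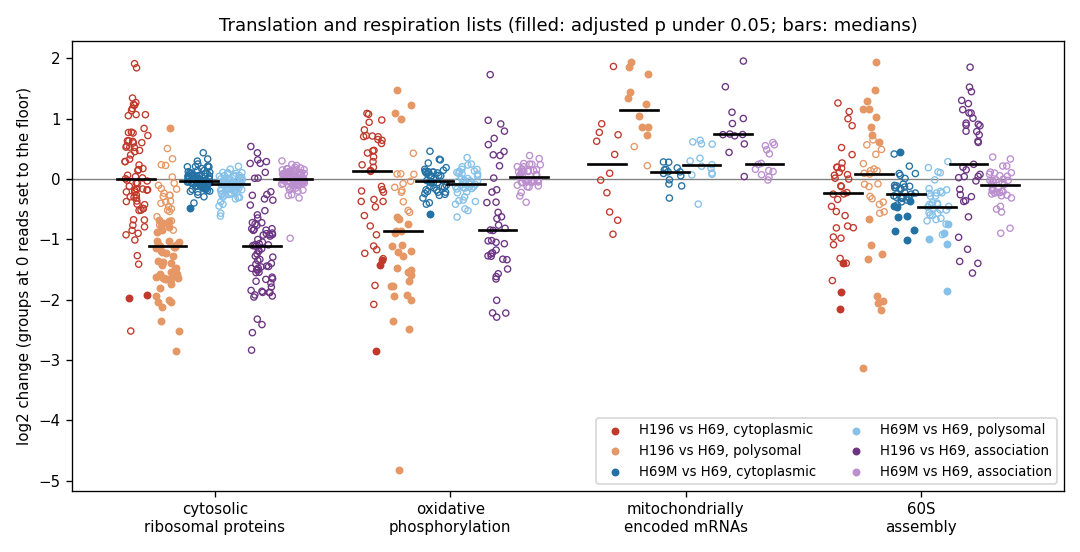
Log2 changes of the members of 4 lists of translation and respiration genes for each comparison and for polysome association, filled where adjusted p is under 0.05, bars for medians. Ribosomal protein mRNAs had a median of -1.10 in H196 polysomal RNA and -0.08 in H69M polysomal RNA.

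Polysome association in H196 differed from H69 for 0 of 16968 genes by edgeR, with 1344 genes at an unadjusted p under 0.05. DESeq2 called 20 higher and 3 lower, limma-voom 0 and 0, and voom with quality weights 471 and 530. Among lists, ribosomal protein mRNAs had lower association (median log2 -1.10, 77 tested, 0 called singly, camera adjusted p = 8.48e-11; adjusted p = 0.667 with an estimated correlation). Oxidative phosphorylation genes were lower too (median -0.84, camera adjusted p = 0.00439; adjusted p = 0.667 with an estimated correlation). Mesenchymal genes (median log2 1.27) and mitochondrially encoded mRNAs (0.74) had higher association, each with camera adjusted p = 0.000606 and each with adjusted p = 0.429 with an estimated correlation. Mitochondrially encoded mRNAs are translated inside mitochondria, so their value does not measure loading on cytoplasmic ribosomes. Mitochondrial reads made up 0.289% to 0.55% of polysomal libraries in this set. They made up 15.4% of H69 cytoplasmic replicate 3, against 7.29% and 7.25% in replicates 1 and 2. Some mesenchymal genes had almost no reads in H69, so that their H69 ratio was not measured and their value rests on the floor. Over the 29 of 39 mesenchymal genes with more than 3 reads in each group the median was 1.00 (camera adjusted p = 0.0232; adjusted p = 0.4 with an estimated correlation). With each polysomal library paired to its cytoplasmic one, snoRNA host RNAs were lower as well (camera adjusted p = 0.015, against 0.0683 unpaired; adjusted p = 0.753 with an estimated correlation). Without H69 replicate 3 the focal adhesion (camera adjusted p = 0.00114) and glycolysis (0.00291) lists were called higher, against 0.0932 and 0.262 with it, and each had adjusted p = 0.647 with an estimated correlation. VIM had 0 cytoplasmic reads in H69, so its H69 ratio was not measured. Its log2 change was -0.63 as fitted, without a usable standard error, or 2.63 with its H69 cytoplasmic group set to the floor.

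In H69M cytoplasmic RNA VIM rose at least 23246-fold, the secreted glycoprotein gene FSTL1 at least 44713-fold. Among 39 mesenchymal genes 35 rose and 4 were not called, also adjusted over the list alone (median log2 6.95, camera adjusted p = 8.29e-32). CHGA stood at log2 -0.23 ± 0.14, SYP at -0.17 ± 0.17, EPCAM at -0.19 ± 0.14 and CDH1 at -0.31 ± 0.17. With the GC trend removed CHGA was called lower (-0.35, adjusted p = 0.0296). Neuroendocrine genes fell in 13 of 25 cases with 12 not called (16 adjusted over the list alone; median log2 -0.56), the kinesin gene KIF1A 2.05-fold and TMSB15A 2.79-fold (camera adjusted p = 4.99e-06; adjusted p = 0.22 with an estimated correlation). Non-neuroendocrine genes rose in 23 of 24 cases, also adjusted over the list alone, CAV1 at least 21006-fold (median log2 6.35, camera adjusted p = 1.67e-23). Lineage regulators rose in 5 of 16 cases and fell in 7, also adjusted over the list alone. YAP1 was at least 2231-fold and WWTR1 at least 1346-fold higher, MYC 11.6-fold higher and MYCN 2.30-fold lower. That list had a median log2 of -0.17, a mean of 1.55 and camera adjusted p = 0.943 downward. In the Notch list 8 of 19 rose and 5 fell (8 and 6 adjusted over the list alone), with a median of -0.13, a mean of 1.04 and camera adjusted p = 0.449 upward. REST rose at least 334-fold, NOTCH3 64.9-fold and HES1 5.70-fold, and the ligand gene DLL1 fell 2.18-fold.

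YAP/TAZ targets rose in 20 of 21 cases in H69M cytoplasmic RNA, also adjusted over the list alone, the matricellular gene CTGF by log2 14.01 ± 0.56 and ANKRD1 at least 1562-fold (camera adjusted p = 6.77e-18; adjusted p = 0.0853 with an estimated correlation). Focal adhesion genes rose in 30 of 35 cases and fell in 3, also adjusted over the list alone, ITGA2 at least 604-fold (camera adjusted p = 6.96e-22). Receptor tyrosine kinase and ERK genes rose in 17 of 25 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 3.25e-08; adjusted p = 0.0853 with an estimated correlation). AXL rose by log2 11.37 ± 0.24, EPHA2 by 12.16 ± 0.33 and CD44 11.6-fold. Antigen presentation and interferon genes rose in 24 of 29 cases with 5 not called (26 adjusted over the list alone), the STING gene TMEM173 40.1-fold and IFIT3 38.9-fold (camera adjusted p = 9.21e-13). Epithelial genes rose in 4 of 22 cases and fell in 6, also adjusted over the list alone, CDH3 116-fold higher and ELF3 3.17-fold lower. The list median was -0.29, the mean 0.09 and camera adjusted p = 0.19 downward. Drug transport and detoxification genes rose in 9 of 17 cases, also adjusted over the list alone, ABCC3 67.2-fold, and 1, ALDH1A1, fell 2.00-fold (camera adjusted p = 0.0208; adjusted p = 0.183 with an estimated correlation).

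Endoplasmic reticulum chaperones rose in 15 of 21 cases in H69M cytoplasmic RNA with 6 not called (16 adjusted over the list alone), PDIA4 3.05-fold and HSPA5 2.42-fold (camera adjusted p = 2.31e-06; adjusted p = 0.382 with an estimated correlation). Glycolysis genes fell in 11 of 22 cases, with 1 rise, the glucose transporter gene SLC2A1 (2.46-fold), also adjusted over the list alone (camera adjusted p = 0.000855; adjusted p = 0.609 with an estimated correlation). ALDOC fell 6.32-fold and the hexokinase gene HK2 3.17-fold. The 60S assembly list fell in 8 of 37 cases and 1, EIF6, rose (6 and 1 adjusted over the list alone), the nucleolar genes BOP1 2.01-fold and NCL 1.82-fold lower (camera adjusted p = 0.00195; adjusted p = 0.609 with an estimated correlation). Proliferation genes fell in 9 of 33 cases and 1 rose (10 and 1 adjusted over the list alone), CCNE2 2.41-fold and MCM4 2.33-fold (camera adjusted p = 0.00475; adjusted p = 0.689 with an estimated correlation). Lipid synthesis genes fell in 6 of 22 cases and rose in 2, also adjusted over the list alone, HMGCS1 2.37-fold lower (camera adjusted p = 0.0353; adjusted p = 0.736 with an estimated correlation). Other 5 prime TOP mRNAs fell in 4 of 23 cases, also adjusted over the list alone, PABPC1 by log2 -0.82 ± 0.14 and EIF4B by -0.63 ± 0.13 (camera adjusted p = 0.0594). ATF4 targets split with 8 of 25 up and 9 down (9 and 9 adjusted over the list alone; camera adjusted p = 0.859), SLC1A5 10.4-fold higher and DDIT4 6.32-fold lower. Across 19145 genes 3093 rose and 2187 fell (58.6% higher). Top rises included CNN1 (at least 9787-fold) and COL5A3 (at least 5590.01-fold). The carbonic anhydrase gene CA9 fell 40.4-fold, HPCA 37.7-fold, ANOS1 21.8-fold, FABP7 19.2-fold and the neurotensin gene NTS 19.0-fold. With library totals 2581 rose and 3241 fell (44.3% higher; median of all genes shifted by -0.13). With the H69 libraries of the H196 set as control 2010 rose and 283 fell, and DLL1, at 0 reads in those libraries, turned upward (fitted log2 12.53, a value not bounded by any control read). With those libraries calls ended for CA9, KIF1A, MYCN, HES1, ELF3, ALDH1A1, PDIA4, HSPA5, CCNE2, NCL, BOP1, ALDOC, SLC2A1, HMGCS1, SLC1A5, DDIT4, PABPC1, EIF4B and EIF6 (log2 -6.83 to 2.05).

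In H69M polysomal RNA VIM rose with a ratio of 41521 to its 2 H69 reads (counting interval 11494 to 342855). Among mesenchymal genes 34 of 39 rose with 5 not called, also adjusted over the list alone (median log2 6.29, camera adjusted p = 7.94e-45; adjusted p = 0.0508 with an estimated correlation). YAP1 rose at least 447-fold, AXL at least 6059.9-fold and MYOF at least 1598-fold. CHGA had log2 -0.03 ± 0.22, SYP 0.23 ± 0.27, EPCAM 0.35 ± 0.37 and HES1 1.16 ± 0.43 (adjusted p = 0.122). With the H69 libraries of the H196 set as control CHGA (5.16), SYP (1.27) and EPCAM (-1.12) were called. Of 25 neuroendocrine genes 1, KIF1A, fell (log2 -0.99 ± 0.29, adjusted p = 0.0464; 0 adjusted over the list alone; camera adjusted p = 0.216). Non-neuroendocrine genes rose in 21 of 22 cases, also adjusted over the list alone (camera adjusted p = 5.41e-30; adjusted p = 0.0743 with an estimated correlation). YAP/TAZ targets rose in 17 of 21 cases and 1 fell, also adjusted over the list alone (camera adjusted p = 3.02e-19; adjusted p = 0.141 with an estimated correlation). Focal adhesion genes rose in 25 of 35 cases and 1 fell (29 and 1 adjusted over the list alone), ITGA5 by log2 12.21 ± 0.60 (camera adjusted p = 6.06e-27; adjusted p = 0.0508 with an estimated correlation). Receptor tyrosine kinase and ERK genes rose in 17 of 24 cases (17 rose and 1 fell adjusted over the list alone), EPHA2 by log2 9.71 ± 0.37 (camera adjusted p = 5.44e-14; adjusted p = 0.0508 with an estimated correlation).

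In the same polysomal RNA NOTCH3 rose 208-fold and its ligand gene JAG1 35.3-fold, with 5 of 19 Notch genes up and 3 down (7 and 4 adjusted over the list alone; camera adjusted p = 0.193). Lineage regulators rose in 4 of 16 cases and fell in 2, also adjusted over the list alone, MYCN 2.52-fold lower (camera adjusted p = 0.34). Epithelial genes rose in 2 and fell in 2 of 22 cases (3 and 3 adjusted over the list alone; camera adjusted p = 0.776), CDH3 86.8-fold higher. Antigen presentation and interferon genes rose in 14 of 27 cases (17 rose and 1 fell adjusted over the list alone), TMEM173 34.4-fold and ISG15 9.87-fold (camera adjusted p = 9.33e-11; adjusted p = 0.141 with an estimated correlation). Drug transport and detoxification genes rose in 4 of 16 cases (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00266; adjusted p = 0.455 with an estimated correlation). Chaperones rose in 3 of 21 cases (4 adjusted over the list alone; camera adjusted p = 0.00139; adjusted p = 0.527 with an estimated correlation). The 60S assembly list fell in 5 of 37 cases, also adjusted over the list alone, NCL 3.62-fold (median log2 -0.45, camera adjusted p = 5.87e-06; adjusted p = 0.0534 with an estimated correlation). Glycolysis genes fell in 6 of 22 cases (7 adjusted over the list alone), ALDOC 5.49-fold (camera adjusted p = 2.45e-05; adjusted p = 0.455 with an estimated correlation). Proliferation genes fell in 7 of 33 cases, also adjusted over the list alone, MCM4 2.67-fold (camera adjusted p = 0.000145; adjusted p = 0.322 with an estimated correlation). ATF4 targets rose in 4 of 25 cases and fell in 2 (5 and 5 adjusted over the list alone), SLC1A5 5.97-fold higher (camera adjusted p = 0.636).

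Ribosomal protein mRNAs were not called singly in H69M polysomal RNA (0 of 79 by edgeR, 0 adjusted over the list alone, median log2 -0.08, camera adjusted p = 0.0801). With libraries of like number paired, these mRNAs (camera adjusted p = 0.0437), other 5 prime TOP mRNAs (0.0136), initiation factors (0.0398) and lipid synthesis genes (0.0398) were lower as lists, against 0.0801, 0.0531, 0.0639 and 0.0801 unpaired. In all 4 the call was lost again with an estimated correlation (adjusted p = 0.896, adjusted p = 0.489, adjusted p = 0.416 and adjusted p = 0.567 with an estimated correlation). Across 16932 genes 1213 rose and 657 fell. The top rises included COL5A3 (at least 11483-fold), CALD1 (at least 2438-fold) and the keratin gene KRT17 (ratio 33349, counting interval 9232 to 275382). CA9 fell 44.6-fold, HPCA 34.2-fold, FABP7 28.0-fold, MPPED2 16.7-fold and NTS 16.5-fold. The fall of KIF1A was not called without H69 replicate 5 or 6 or H69M replicate 1, 2 or 3 (log2 -1.15 to -0.78), nor with DESeq2 size factors (-0.97) or the other H69 libraries (-0.60). HES1 was called without H69M replicate 2 (1.54) and by DESeq2 (1.19). The count of falls was 384 without H69 replicate 6, 405 without H69M replicate 2 and 398 without H69M replicate 3.

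Polysome association in H69M changed for 2 of 19800 genes by edgeR, with 1185 at an unadjusted p under 0.05, and DESeq2 called 8 higher and 21 lower. MAP3K9, a kinase upstream of JNK signalling, rose in association by log2 2.64 ± 0.36 (adjusted p = 0.0244). H69 had 58.1 CPM in cytoplasmic and 11.2 in polysomal RNA, H69M 56.3 and 67.8. H69 itself ran the other way in the H196 set, where MAP3K9 stood at 49.8 CPM of library totals in cytoplasmic and 87.2 in polysomal RNA, against 74.8 and 8.90 for H69 here. The rise in H69M thus rests on a low polysomal H69 value not seen in the other H69 libraries. TCEB1P2, a pseudogene outside the naming rule and named after its values were seen, fell in association, with 0 reads in H69M polysomal RNA (adjusted p = 0.00195). With a block for library pairs both calls ended (0 higher, 0 lower), whereas a log2 ratio per library pair gave 2 higher and 19 lower, with TCEB1P2 still called. Both settings pair libraries by number, which the pairing check did not bear out for H69M (r = -0.12, 0.24 and -0.16). The call ended for MAP3K9 with that ratio (2.65), without H69 replicate 4, 5 or 6 or H69M replicate 2 or 3 (log2 2.28 to 2.79), and for TCEB1P2 without H69 replicate 4. Without H69M replicate 1 association was higher for 1 gene and lower for 8.

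As lists, neuroendocrine genes had higher association in H69M (median log2 0.43, camera adjusted p = 2.54e-07; adjusted p = 0.357 with an estimated correlation), as did epithelial genes (median 0.39, camera adjusted p = 0.0261; adjusted p = 0.938 with an estimated correlation). Non-neuroendocrine genes (median -1.26, camera adjusted p = 0.00231), YAP/TAZ targets (-0.67, 0.0261), focal adhesion genes (-0.19, 0.00499) and antigen presentation and interferon genes (-0.28, 0.00215) had lower association, each with adjusted p = 0.938 with an estimated correlation. Members of these lists with almost no reads in H69, such as YAP1, have no measured H69 ratio and enter the medians at the floor. Over members with more than 3 reads in each group the medians were -0.95 for 17 of 24 non-neuroendocrine genes (camera adjusted p = 0.0219; adjusted p = 0.863 with an estimated correlation) and -0.33 for 15 of 21 YAP/TAZ targets (0.0335; adjusted p = 0.88 with an estimated correlation). For 31 of 35 focal adhesion genes the median was -0.11 (camera adjusted p = 0.0214) and for 25 of 30 antigen presentation and interferon genes -0.31 (0.000881), each with adjusted p = 0.585 with an estimated correlation. Members called singly numbered 0 in each of these lists, and adjusted over the list alone 1 neuroendocrine gene rose and 1 YAP/TAZ target fell. Ribosomal protein mRNAs had a median of 0.01 (camera adjusted p = 0.902).

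Both lines shared many changes against their own H69 libraries. H69 was the reference line in both comparisons, so more shared changes than from independent calls, and a positive r, are partly built in. They do not alone show a common change of H196 and H69M. In cytoplasmic RNA, among 15091 genes tested in both, 1408 rose in both (376 expected from independent calls), 1084 fell in both (369 expected) and 173 moved in opposite directions. Across genes, which are not independent replicates, r was 0.63. In polysomal RNA, among 14048 genes, 928 rose in both (301 expected), 326 fell in both (210.5 expected) and 173 were opposite (r = 0.56 across genes). The test of the difference in cytoplasmic RNA called 3329 of 20036 genes with a higher H69M than H196 effect and 1320 with a lower one, where the median difference of all genes was 0.29. Of the neuroendocrine genes 21 of 25 had the higher effect in H69M and 4 were not called (22 adjusted over the list alone; median difference 6.98, camera adjusted p = 1.34e-13). Epithelial genes had the higher effect in H69M in 15 of 22 cases (16 adjusted over the list alone; camera adjusted p = 5.67e-06; adjusted p = 0.352 with an estimated correlation). Lineage regulators did so in 9 of 17 cases, also adjusted over the list alone (camera adjusted p = 0.000203; adjusted p = 0.0844 with an estimated correlation). Antigen presentation and interferon genes had the lower effect in H69M in 15 of 31 cases (1 higher and 17 lower adjusted over the list alone; camera adjusted p = 3.08e-06; adjusted p = 0.111 with an estimated correlation). Without H69 replicate 3 of the H196 set 5383 genes had the higher and 2816 the lower effect, and initiation factors were lower as a list (camera adjusted p = 0.0141, against 0.0953 with it; adjusted p = 0.492 with an estimated correlation). Mesenchymal genes had the lower effect in H69M in 9 of 39 cases and the higher in 5, also adjusted over the list alone (camera adjusted p = 0.0164; adjusted p = 0.352 with an estimated correlation). Drug transport genes were lower in 7 and higher in 3 of 22 cases (7 and 4 adjusted over the list alone; camera adjusted p = 0.0113; adjusted p = 0.196 with an estimated correlation). That call was lost over the 17 drug transport genes with more than 3 reads in H69 of both sets (camera adjusted p = 0.121). Proliferation genes were lower in 5 and higher in 1 of 33 cases (4 and 1 adjusted over the list alone; camera adjusted p = 0.0287; adjusted p = 0.352 with an estimated correlation). Lipid synthesis genes were lower in 3 of 22 cases (2 adjusted over the list alone; camera adjusted p = 0.0287; adjusted p = 0.595 with an estimated correlation). Nuclear long noncoding RNAs were higher in 2 of 6 cases (4 adjusted over the list alone; camera adjusted p = 0.0416; adjusted p = 0.196 with an estimated correlation).

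In polysomal RNA 5359 of 17455 genes had the higher and 2551 the lower effect in H69M (67.7% higher, median difference of all genes 0.43). With library totals the counts were 6689 and 1725 (79.5% higher, median shifted by 0.42), and DESeq2 size factors shifted the median by -0.22. Ribosomal protein mRNAs had the higher effect in H69M in 45 of 79 cases with 34 not called (46 adjusted over the list alone; median difference 1.15, camera adjusted p = 0.000446; adjusted p = 0.644 with an estimated correlation). Neuroendocrine genes differed in 22 of 25 cases, all higher in H69M (23 adjusted over the list alone; camera adjusted p = 4.92e-13). Epithelial genes were higher in 19 of 22, also adjusted over the list alone (camera adjusted p = 3.89e-08; adjusted p = 0.14 with an estimated correlation). Lineage regulators had the higher effect in 10 of 17 cases and the lower in 1, also adjusted over the list alone (camera adjusted p = 0.0138; adjusted p = 0.14 with an estimated correlation). Mesenchymal genes had the lower effect in H69M in 15 of 39 cases and the higher in 3, also adjusted over the list alone (camera adjusted p = 4.34e-05; adjusted p = 0.375 with an estimated correlation). Focal adhesion genes were lower in 15 of 35 cases and higher in 2, also adjusted over the list alone (camera adjusted p = 4.93e-05; adjusted p = 0.14 with an estimated correlation). Antigen presentation and interferon genes were lower in 18 and higher in 1 of 31, also adjusted over the list alone (camera adjusted p = 1.98e-08; adjusted p = 0.14 with an estimated correlation). Proliferation genes were lower in 11 of 33 cases and higher in 5, also adjusted over the list alone (camera adjusted p = 0.00484; adjusted p = 0.644 with an estimated correlation). YAP/TAZ targets were lower in 5 and higher in 1 of 21, also adjusted over the list alone (camera adjusted p = 0.0218; adjusted p = 0.644 with an estimated correlation). The YAP/TAZ call was lost over the 14 targets with more than 3 reads in H69 of both sets (camera adjusted p = 0.124). Drug transport genes were lower in 8 of 21 cases and higher in 4 (camera adjusted p = 0.00299; adjusted p = 0.425 with an estimated correlation). Lipid synthesis genes were lower in 7 and higher in 1 of 22 (camera adjusted p = 0.00484; adjusted p = 0.472 with an estimated correlation), and both counts were the same adjusted over the list alone.

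The fractions were checked with mitochondrially encoded mRNAs and the nuclear RNA MALAT1, which ribosomes of the cytoplasm do not translate. Mitochondrially encoded mRNAs, translated inside mitochondria, were lower in polysomal than in cytoplasmic RNA, with list medians of log2 -4.57 in H69 and -3.66 in H196 of the H196 set, -3.17 in H69 and -2.96 in H69M of the other set. MALAT1 was lower by log2 -4.21, -3.81, -5.67 and -5.48 in the same order. It was itself present in cytoplasmic RNA, with a mean of 8.32 log2 CPM over the cytoplasmic libraries of both sets. The check thus does not show that cytoplasmic RNA was free of nuclear RNA, and whether its share differed between lines was not tested. The snoRNA host RNAs, which can meet cytoplasmic ribosomes and so do not test the fractions in the same way, had medians of -2.13, -2.76, -0.95 and -1.01. Between lines, MALAT1 in cytoplasmic RNA fell 14.7-fold in H196, MEG3 fell with a ratio of 0.000162 (counting interval 1.96e-05 to 0.000584). Of 6 nuclear long noncoding RNAs 4 fell (5 adjusted over the list alone; camera adjusted p = 0.0159; adjusted p = 0.132 with an estimated correlation). In H196 polysomal RNA snoRNA host RNAs fell in 7 of 13 cases (6 adjusted over the list alone; camera adjusted p = 0.178), SNHG1 5.56-fold. Ribosomal protein mRNAs stood lower in polysomal RNA of H69 in the H196 set (median log2 -0.73) and higher in that of H69 in the H69M set (1.15), so that the same line gave opposite values in the 2 sets. In total 140 genes were higher and 377 lower in polysomal RNA for H69 of the H196 set (0 and 53 with libraries paired). The counts were 1242 and 1530 for H196 (1616 and 1581 with libraries paired, so that the balance turned). They were 5834 and 6534 for H69 of the H69M set (5814 and 6405 paired) and 5676 and 6655 for H69M (5575 and 6471 paired).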

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

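Tests of loss of molecules regardless of GC content, of a library of H196 cells under the H69 label, of H196 cells mixed into H69M and of line labels split within each set were chosen after the result was seen.

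The results here stand out because the test of the difference between the 2 comparisons was called, with each line measured against its own H69 libraries. In cytoplasmic RNA the H69M effect was above the H196 effect for 3329 genes and below it for 1320. Genes with no reads in H196 gave differences of at least 11.28 for MS4A8, 10.33 for NTM, 9.91 for NRIP1, 9.72 for SDK2 and 9.56 for WBSCR17 on the log2 scale. The differences were 10.85 for EPCAM, 8.50 for ALDH1A1, 8.02 for ERO1B, 6.49 for CCND1 and 1.96 for CDH1, which was not called without H196 replicate 3 or H69 replicate 6 of the H69M set (1.87 in each case). The H196 effect was above the H69M effect by log2 differences of -9.71 for STAT6, -9.20 for ENPP2, -8.95 for CAPG and -7.81 for NOTCH3, and of at most -12.24 for ATL3 and -9.08 for C14orf64 (both at 0 in H69M) and -6.44 for IFITM3 (at 0 in H69 of the H196 set).

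In polysomal RNA the H69M effect was above the H196 effect for 5359 genes and below it for 2551. Differences were at least 11.58 for SYT4, 11.37 for HEPACAM2, 10.68 for KCNA1, 10.58 for SLC35D3 and 10.38 for HTR3A, all at 0 in H196, and 11.52 for EPCAM, 8.08 for ALDH1A1 and 5.98 for CCND1. RPS26 (2.88), RPS25 (2.87) and ATP5D (2.82), which fell in H196, also differed. Negative differences were -10.80 for ATL3, -9.78 for MOCS1, -9.45 for GUCY1B3, -8.68 for STAT6, -4.78 for NOTCH3, at most -9.39 for ENPP2 (at 0 in H69M) and -1.63 for HES1. HES1 was not called with library totals (-1.18), nor without H69 replicate 2 of the H196 set (-1.54), H196 replicate 3 (-1.39), H69 replicate 5 (-1.40) or H69M replicate 2 (-1.30) or 3 (-1.37).

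H69 cytoplasmic replicate 3 of the H196 set stood apart from replicates 1 and 2. Its log2 ratio to their mean followed GC content with a Spearman rho of -0.84 across genes, the value a GC bias of this library predicts. Replicates 1 and 2 gave rho of 0.71 and 0.82. Each was set against a mean that contained replicate 3, so these values are not independent of it. Loss of molecules regardless of GC content is argued against by a ratio of 79.7 between the shares of genes at 0 reads in high-GC (33.8% of 470) and low-GC (0.425% of 471) coding genes. A library of H196 cells under this label is argued against by 0% of 63 H196-only genes that reached 10% of their H196 level. What gave rise to the GC trend stays open, and no biological explanation was tested.

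Mesenchymal genes rose in H69M beside neuroendocrine genes with cytoplasmic log2 changes from -1.48 (TMSB15A) to 0.19 (RTN1). If H196 cells were mixed into H69M, abundant H196-only genes would follow the mesenchymal median share of 57.6% of the H196 level, but 66.1% of 59 such genes lay far below it (under 10% of that share), as did 67.3% of the 55 outside the mesenchymal list. These shares compare levels between the sets. In H69 cytoplasmic RNA 320 genes were over 16-fold higher and 0 over 16-fold lower in the H69M set. Of the 59 genes 13 had at most 3 reads in H69M, and a difference in counting between the sets is not excluded for them. A loss of all neuroendocrine genes by 1 factor through any mixture is argued against by a mean squared deviation of 5.27 in units of squared standard errors over 25 genes (weighted mean log2 -0.47). A mixture of H69 cells with cells of another line or state that still express neuroendocrine genes stays open, as does a change of state of the H69M cells, which was not tested.

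Ribosomal protein mRNAs were lower in H196 polysomal RNA, with a list median of -1.10. Annotated transcript length is argued against by a difference of -1.26 from the median of 1000 draws of genes matched on length and expression (0.16; range of the central 95% of draws -0.20 to 0.59). Length was that of the longest coding transcript annotated for each gene. The lengths of the transcripts present in the cells and of their reading frames were not matched, so an effect of those stays open. A GC trend between libraries is argued against by a list median of -1.15 with that trend removed, where 54 of 74 genes were lower and 1 higher. Polysomal over cytoplasmic levels of these mRNAs had opposite signs in H69 of the H196 set and H69 of the H69M set, so they varied within the same line. The cause of that variation was not tested, and whether it bears on the H196 value stays open. Reads shared with pseudogenes stay open, and so does a difference in translation between the lines, which was not tested.

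For a comparison of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. The real calls were 5654 (H196 cytoplasmic), 9845 (H196 polysomal), 5280 (H69M cytoplasmic), 1870 (H69M polysomal) and 2 (H69M association), where 1 of 10 splits, the real one, gave as many and the highest other gave 0. For H196 association the real value was 0 and all 10 splits gave as many.

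For the differences between effects, line labels were split within each set, the real split and 99 others. As many calls came from 7 of 100 splits in cytoplasmic RNA (real 4649, highest other 6164) and from 10 of 100 in polysomal RNA (real 7910, highest other 8830), so that chance is not excluded by this count. The other splits with as many calls all kept the real H196 labels beside mixed H69M labels, and the 88 splits with mixed H196 labels gave at most 4 calls in cytoplasmic and 0 in polysomal RNA. The counts of differences thus follow the H196 labels. Splits that kept the real H196 labels set the H196 effect against mixed H69M labels, so many calls are built into them. They hold no case of equal effects, so this count cannot decide whether the H69M effect differs from the H196 effect. An exchange of H69M with H196 libraries, with H69 left in place, gave 0 calls in each of the splits other than the real one, but 10 such splits are too few for a share under 0.05.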

How the results depend on the processing

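Quality weights, robust quasi-likelihood, removal of the GC trend, list tests limited to members with more than 3 reads and the omission of H69 cytoplasmic replicate 3 of the H196 set were chosen after seeing the data. Low recovery of 4-fold changes in H196 cytoplasmic RNA (1.49%) and H196 association (1.49%) limits what a missing call there shows. The simulation changed only 66 or 67 genes per fold, whereas 5654 genes were called in real H196 cytoplasmic RNA. Adjustment was therefore stricter in the simulation, and its recovery is not that of the real cytoplasmic test. With 3 libraries per group single libraries moved several counts. For named genes, 4075 of 4191 values under the alternatives kept direction and side of the threshold, 86 lost and 8 gained a call and 22 changed sign; of the latter 1, DLL1, was a called gene. For lists called in at least 1 setting, 249 of 340 values stayed, 65 lost and 26 gained a call, 62 of the losses with an estimated correlation. The limit to members with more than 3 reads left 31 of 43 such values as they were, with 2 losses and 10 gains (adjusted p = 0.00943 to 0.0472), and each gained call was lost with an estimated correlation (adjusted p = 0.26 or more). Without H69 replicate 3 no H196 cytoplasmic list was called with an estimated correlation (adjusted p = 0.124 or more), the neuroendocrine and mesenchymal ones included. Pairing by library number changed no list call beyond those given with the results, except nuclear long noncoding RNAs in H196 polysomal RNA (camera adjusted p = 0.0438 against 0.0832), where numbers do not pair. The cause was not tested for any change below, except that a threshold on the fold or on reads leaves fewer genes by construction.

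Counts (higher and lower) moved as follows. With the H69 libraries of the other set: H196 cytoplasmic 5969 and 7218, H69M cytoplasmic 2010 and 283, H69M polysomal 4949 and 5103. With quality weights: H196 cytoplasmic 4675 and 4578, H196 association 471 and 530, H69M polysomal 1386 lower, H69M association 28 and 51, the cytoplasmic difference 5665 and 3738, the polysomal difference 3887 lower. DESeq2 gave 20 and 3 for H196 association, 8 and 21 for H69M association and 2061 lower for the cytoplasmic difference, for which limma-voom gave 2001 and the removed GC trend 2428. No filter gave 11 and 8 (H196 association) and 2 and 2 (H69M association), the removed GC trend 1 higher and 2 and 2, and the omission of cytoplasmic library 3 alone 1 higher in H196 association. An absolute log2 change of at least 1 gave 1948 and 796 (H69M cytoplasmic), a shared dispersion 1046 lower (H69M polysomal). For H69M association a filter at 50 reads gave 0 lower, the block 0 and 0, a ratio per library pair 2 and 19. With 1 library left out, ranges were 1910 to 4459 and 2033 to 5027 for H196 cytoplasmic (highest without H69 replicate 3), 384 to 648 lower for H69M polysomal, 0 to 1 and 0 to 8 for H69M association (8 without H69M replicate 1), and 2574 to 5383 and 885 to 2816 for the cytoplasmic difference (highest without H69 replicate 3 of the H196 set).

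Signs reversed with the other H69 libraries for EIF6 (-0.52, H196 cytoplasmic), ATF4 (0.55, H196 cytoplasmic), CHGA (2.20), SYP (0.59) and DLL1 (12.53 as fitted over a control at 0 reads) in H69M cytoplasmic RNA, and CHGA (5.16) and EPCAM (-1.12) in H69M polysomal RNA, where both were called, as was SYP (1.27). ATF4 in H196 cytoplasmic RNA was 0.41 by limma-voom, 0.35 with the block and -0.65 to 0.99 with 1 library left out. VIM in H196 association, fitted over H69 cytoplasmic libraries at 0 reads, was 0.0577 by DESeq2, 0.60 by limma-voom, 1.16 as a ratio per pair, 0.34 with quality weights and -1.12 to 1.12 with 1 library left out. In H69M polysomal RNA EIF6 was -0.0123 with quality weights, CHGA 0.0142 with no filter, 0.0106 with quality weights and -0.10 to 0.0613 with 1 library left out, and EPCAM -0.0395 to 0.96 with 1 library left out.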

Other observations

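Markers of cells that do not belong in the cultures entered each test in small numbers. The endothelial marker CLDN5 was abundant, with a mean of 6.07 log2 CPM over the cytoplasmic libraries of both sets. Its H69M effect minus its H196 effect was log2 11.17 ± 2.05 in cytoplasmic RNA (adjusted p = 0.00177 by edgeR). Of the blood cell markers, 1 of 5 tested rose in H69M cytoplasmic and in H69M polysomal RNA (1 adjusted over the list alone in each; camera adjusted p = 0.859 and 0.384), with 0 of 1 and 0 of 2 called in H196 cytoplasmic and polysomal RNA by edgeR. Of the endothelial markers, 2 of 4 rose in H69M cytoplasmic RNA and 0 of 3 changed in polysomal RNA (camera adjusted p = 0.372 and 0.859), 1 of 2 rose in H196 cytoplasmic RNA, and 1 of 3 rose and 2 fell in H196 polysomal RNA (camera adjusted p = 0.829).

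The H69 libraries of both sets differed from each other. In cytoplasmic RNA 832 of 17799 genes were higher and 9 lower in the H69M set, 320 of them over 16-fold higher, and in polysomal RNA 4644 of 15798 were higher and 4377 lower. Cytoplasmic H69 of the H196 set had 0 reads of EEF1G, an elongation factor gene, against 607 CPM in the H69M set, and the same held for MIF (321 CPM), TUBB (114 CPM), SMARCB1 (108 CPM), DLL1 (70.9 CPM) and PSMB3 (67.4 CPM). Whether the tables of the sets were counted with the same settings is not stated in the labels.

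Within a line both fractions moved alike across genes. In H196, 2255 genes rose and 2560 fell in both fractions, with 1 opposite among 14227 genes (r = 0.95 across genes). In H69M, 1173 rose and 523 fell in both, with 0 opposite (r = 0.93 across genes).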
